A study of Mus musculus with 4 samples.

How the data were processed

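Gene expression was measured on 4 Affymetrix whole-transcript mouse arrays. Gliomas were induced in C57/Bl6 mice with a retrovirus carrying PDGF-B and EGFP, injected at embryonic day 14, and EGFP-positive cells were sorted by flow cytometry from the dissociated tumours, per the labels' protocols. The 2 early-onset samples were labelled low-grade, and each was a pool of cells from 2 tumours. The 2 late-onset samples were labelled high-grade, and each came from 1 tumour. Total RNA was extracted with Trizol and RNeasy columns and biotinylated by the one-cycle protocol, per the labels' protocols.

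The deposited values were log2 probe set summaries. RMA and affy version 3.4.2 were named in the submitters' processing notes, with no parameters. The 34760 probe sets had log2 values from 2.17 to 14.8, and the medians of the 4 columns lay between 6.63 and 6.71. RMA subtracts background and scales arrays to one distribution, so a change shared by most genes cannot be seen, and the fold change of a dim gene is understated. The number of arrays, 2 per group, limits the precision. The labels call the samples biological replicates, and the replicate numbers only name samples.

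Probe sets were named through the platform annotation. A single gene symbol was given for 21640 probe sets, several for 1321 and none for 11799. Of the single-gene probe sets, 21553 matched a gene of the mouse GRCm38.p6 RefSeq table by Entrez identifier, and 0 symbols changed. Probe sets with several genes or none were left out of the tests. Each gene was represented by its probe set with the highest mean over the 4 arrays, which left 19937 genes, of which 954 had more than 1 probe set. For 0 called genes was another probe set called in the opposite direction.

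The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), as late-onset minus early-onset. The deposited values entered without further scaling or filtering, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. The fit had 2 residual degrees of freedom per gene and a prior of 3.27. All adjusted p-values for genes come from this limma fit unless another setting is named. Gene lists were compared with camera from limma, 2-sided, with its preset correlation of 0.01 between genes. Of 50 lists fixed before the data were examined, 49 were tested together with Benjamini-Hochberg adjustment, and the sex-linked list was used as a check only. The lists held 1139 genes, of which 1043 were measured, and a list needed at least 5 measured genes. Counts adjusted over the list alone used only the p-values of the list's members. Intervals of list medians come from 2000 resamples of the genes and cover 95%. They treat genes as independent and say nothing of the spread between tumours.

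The rule for the genes named in the text was fixed before the data were examined. It took the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes whose groups did not overlap and whose mean in the higher group lay above the median of all genes, passing over predicted genes. It took up to 4 called members of each list by absolute log2 fold change, or up to 2 by moderated t where none was called. Pdgfb, Pdgfra, Olig2, Sox10, Gfap, Mki67, Cdkn2a and Cd274 were always included. Genes named outside this rule are said to be chosen after their values were seen.

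On simulated arrays with 200 of 19937 genes changed, tested over 5 runs, the late against early comparison recovered 36.7% of genes with a log2 change of 1 and 96.3% of those with a log2 change of 2. Of the calls, 5.41% and 4.56% were false, respectively. The simulated noise was independent between genes, with variances drawn from the fitted prior. These shares therefore check the procedure and are not the error rate of the calls in the real data. Alternatives covered the variance model, filters on dim genes, scaling between arrays, the choice of probe set, array weights, the replicate number as a block, each sample left out in turn, other thresholds and other list tests. For the chromosome comparison, genes above the median level were placed on chromosomes by the same RefSeq table.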

Results

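Sorted tumour cells from PDGF-B-driven mouse gliomas were profiled on 4 arrays to ask how early-onset low-grade tumours differ from late-onset high-grade ones. PDGF-B is a growth factor that drives glial progenitors to proliferate, and EGFP marked the cells that carried the virus. The early-onset group held 2 pools and the late-onset group 2 single tumours, here called pool 1, pool 2, tumour 1 and tumour 2. Over all probe sets the pools correlated at r = 0.992 and the tumours at r = 0.988, against 0.972 to 0.974 between groups. The first principal component separated the groups and held 79.8% of the variance.

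Transcripts of myeloid cells were far lower in late-onset cells, while other single genes were far higher. The genes that rose most were Clca3a1 (log2 fold change 5.51, SE 0.12) and Clca3a2 (5.32, SE 0.10), a pair of chloride channel accessory genes. Their close sequence similarity leaves open how the signal divides between them. Moxd1, a monooxygenase-like gene of the neural crest, rose from 8.04 ± 0.64 to 12.60 ± 0.15 (mean log2 value ± SD, n = 2). Cd109, which encodes a cell surface protein that binds TGF-beta, rose by 3.79, and the motor gene Myo5b and the basement membrane collagen gene Col18a1 rose by 3.51 and 3.49. The retinoic acid synthesis gene Aldh1a3 (3.25), Emp1 (2.91), the mechanosensitive channel gene Piezo2 (2.88), the matrix genes Postn (2.86) and Tnc (2.54), and Syt4 (2.75) completed the 12. Emp1 stood at 8.36 in tumour 1 and 10.44 in tumour 2, and Aldh1a3 at 9.09 and 10.88. Without tumour 2 their log2 fold changes were 1.86 and 2.35.

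The genes that fell furthest were mostly genes of macrophages and inflammation. Il1a, which encodes interleukin 1 alpha, fell from 10.71 ± 0.65 to 5.58 ± 0.46 (mean log2 value ± SD, n = 2), a 35.2-fold lower level in late-onset cells. Ly86 fell by 4.70, the chemokine gene Ccl3 by 4.64, and Fcrls, a microglial Fc receptor-like gene, by 4.64. Mpeg1 (-4.47), Itgam (-4.23), Clec7a (-4.16) and Csf1r (-4.11), the receptor on which macrophage survival depends, also fell. The complement gene C1qb (-4.10), Cxcl2 (-4.05), Selenop (-4.04) and Cxcl10 (-4.02) completed the 12. In these 24 genes adjusted p ranged from 0.000398 for Clca3a1 to 0.0434 for Emp1.

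In all, 2931 of 19937 genes changed, with 1313 higher and 1618 lower in late-onset cells. Of these, 373 rose and 704 fell by at least 2-fold, and 7 rose and 80 fell by at least 8-fold. The 2 groups did not overlap in 58.9% of genes, against 33.3% by chance. Without pool 1 the count was 943 and without pool 2 it was 850, with the lone pool assumed to vary like the tumours. Among the 24 genes, calls were lost for Aldh1a3 without either pool (adjusted p 0.0873 and 0.127), Emp1 without either pool (0.16 and 0.179), Ccl3 without either pool (0.0546 and 0.0502), Postn without pool 2 (0.0502), and Tnc without pool 2 or tumour 2 (0.113 and 0.0779). With robust eBayes, calls were also lost for Aldh1a3 (adjusted p 0.0541), Emp1 (0.0961) and Tnc (0.0599). Of 165 called genes chosen by the naming rule, 90 lost their call without 1 of the pools, 36 without 1 of the tumours, and 17 under another variance model, scaling, probe set rule or array weighting. Beyond those described with their values, the 17 held Tnfaip3, Mobp, Cd24a, Fdps, Syt1, Pvr, Cd4, Cycs and Prom1. Without tumour 1, further calls were lost for Fdps, Tnfaip3, Tlr4, Klf2, Lgals3, Cd74, Myrf, Prom1, Cd24a, Sox11, Syt1, Pvr, Lfng, Cycs, Trp53inp1, Ccng1, Sesn2 and Cd4 (adjusted p 0.0503 to 0.104). Without tumour 2 they were lost for Fdps, Hmga2, Smarca2, Klf2, Meg3, S100a10, Sox11, Pvr, Dll1, Cycs, Atp5g1, Trp53inp1, Ccng1, Sesn2, Ptprd, Ldha, Cd4, Tgfbr1 and Wnt7a (0.0502 to 0.121).

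**Figure D1:**
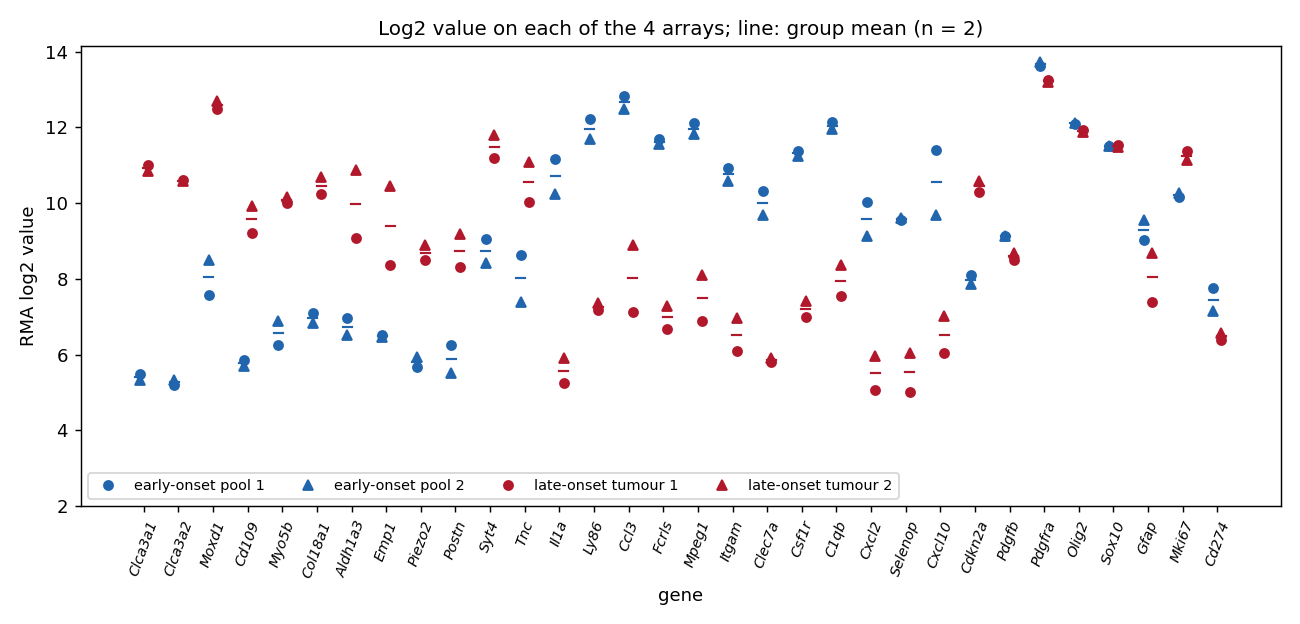
The plot gives the RMA log2 value of the most changed genes and the genes named in advance on each of the 4 arrays, with short lines for group means (n = 2). Pools are blue and tumours red. Mean Csf1r lay at 11.31 in the pools and at 7.20 in the tumours, and Sox10 differed by 0.00.

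Among the lists fixed in advance, 22 of 49 shifted by camera, 10 higher and 12 lower in late-onset cells. With the correlation between genes estimated from the data, 0 of the 49 passed by camera at an adjusted p of 0.05, and 2 had an unadjusted p under 0.05. That test has only the 2 residual degrees of freedom of the fit, which puts an adjusted p of 0.05 almost out of reach. The synapse list's estimated correlation was -0.0261, below the preset 0.01, yet its unadjusted camera p went from 3.24e-08 to 0.0252. Of the 22 lists, only the synapse and chromatin (-0.0388) lists had an estimate below the preset. The others ran from 0.0436 (neuron) to 0.66 (mitosis), so their camera p-values with the preset may be too small. Adjusted p-values with an estimated correlation below therefore do not separate gene correlation from the small number of arrays. By fry, which asks whether a list's own genes move one way, 6 passed. They were microglia and macrophage and ribosome biogenesis (adjusted p 0.0411 each), synapse and chromatin (0.033 each), and 2 that camera did not pass. The other 18 of the 22 lists shifted by camera did not pass fry. Among these, mitosis, DNA replication and DNA repair each had an adjusted p of 0.057 by fry. The counts of members below come from the gene-wise limma fit and do not depend on either list test.

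The microglia and macrophage list moved furthest, with a median log2 fold change of -3.69 over 26 measured genes. Of these, 25 fell and 0 rose, and all 26 fell when adjusted over the list alone. The list spans surface receptors, such as Cx3cr1 (-3.99), Ptprc (-3.30) and Trem2 (-2.24), and the lineage transcription factor gene Spi1 (-2.38), 4 genes chosen after their values were seen. Gene by gene, tumour 2 minus tumour 1 had a median of 0.63, with 21 of the 26 higher in tumour 2. The list's adjusted p was 1.55e-23 by camera and 0.638 with an estimated correlation.

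Inflammatory and antigen presentation genes lay lower with the myeloid genes. Of 33 cytokine and chemokine genes, 14 fell and 0 rose (15 and 1 adjusted over the list alone), at a median of -0.42. That median was -0.27 without pool 1, -0.69 without pool 2 and -1.13 among genes above the lower quartile, and camera passed the list each time. Of 11 genes of MHC class II antigen presentation, 6 fell (7 adjusted over the list alone), at a median of -0.61, among them the protease gene Ctss (-3.74), Ifi30 (-2.18), Lgmn (-1.45) and the invariant chain gene Cd74 (-1.39). Among 19 complement and innate sensor genes, 8 fell and 1 rose (8 and 2 adjusted over the list alone), led by Tlr7 (-3.63), Tlr2 (-3.18), Tnfaip3 (-1.61) and Tlr4 (-1.57). Of 33 interferon response genes, 6 fell (7 adjusted over the list alone), including Trim30a (-2.85), Parp14 (-1.22) and Bst2 (-1.17). Of 17 genes of MHC class I antigen presentation, 3 fell, and 3 when adjusted over the list alone: the peptide loading genes Tapbp (-1.21) and Tap2 (-1.17), and Erap1 (-0.68). Of 22 autophagy and lysosome genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), led by Ctsd (-1.92), Grn (-1.64), Ctsa (-1.10) and Psap (-0.79). With an estimated correlation the adjusted p was 0.638 for the cytokine, both MHC and interferon lists, 0.643 for complement and 0.766 for autophagy and lysosome. Without tumour 1, camera no longer passed complement (adjusted p 0.0678), MHC class I (0.0806) or autophagy and lysosome (0.163). The MHC class I median was then -0.20, and the autophagy and lysosome median was -0.10, against -0.43 without tumour 2.

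Of the other immune lists, none passed camera. Among 26 immune checkpoint and suppressor genes, 7 fell and 2 rose (10 and 5 adjusted over the list alone), and the list passed as lower without pool 2 (adjusted p 0.0203) or tumour 2 (0.0189). The co-stimulatory gene Cd86 (-3.11), Vsir (-2.64) and Havcr2 (-2.51) fell, as did Cd274, which encodes PD-L1 (-0.97, adjusted p 0.0435), whereas the galectin gene Lgals1 rose (2.21). The Cd274 call was lost without pool 1 (adjusted p 0.105), tumour 1 (0.108) or tumour 2 (0.0818), after quantile normalization (0.0572), after cyclic loess (0.0515) and with array weights (0.0512). Of 8 NK cell ligand genes, 3 rose and 1 fell, with the same counts adjusted over the list alone. Raet1d (2.24), H60b (1.76) and Pvr (0.62), which encode ligands of activating NK cell receptors, rose, and Cd48 fell (-3.22). Raet1d belongs to a family of near-identical copies, so how its signal divides between them is open. Of 21 T and NK cell markers, 1 fell, Cd4 (-0.44), and 0 when adjusted over the list alone. Of 16 B cell and granulocyte markers, 2 fell, Blnk (-2.58) and Csf3r (-1.84), and 2 when adjusted over the list alone. The other 14 were not called, and the list median was -0.08. The list's median log2 value was dim on each array, from 5.38 to 5.51, against 7.44 for all genes. That list passed as lower by camera among genes above the lower quartile (adjusted p 0.039) and by fry (0.033). Which cells carried the falls of Blnk and Csf3r was not tested.

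Cell cycle genes rose together in late-onset cells. All 31 measured genes of mitosis and G2/M rose, also when adjusted over the list alone, with a median log2 fold change of 1.11. Nek2 (1.80), Nusap1 (1.38), Aurka (1.37) and Kif20a (1.37), which act in spindle assembly and cytokinesis, rose most, and the proliferation marker Mki67 rose by 1.03 (SE 0.12, adjusted p 0.00853). Of 29 genes of DNA replication and G1/S, 24 rose and 0 fell (28 and 0 adjusted over the list alone), at a median of 0.89, led by Chaf1b (1.36), Mcm3 (1.25), Rrm2 (1.18) and Rfc4 (1.12). Of 22 DNA repair genes, 11 rose (15 adjusted over the list alone), led by Exo1 (1.43), Blm (1.06), Chek2 (1.01) and Rad51ap1 (0.95). With an estimated correlation the adjusted p of each of these 3 lists was 0.638. Nek2, Mcm3 and Exo1 lie on chromosome 1, where tumour 1 stood 0.43 higher, and were at 1.67, 0.95 and 1.19 without tumour 1. Calls were lost without either pool for Mki67 (0.97 without pool 1 and 1.09 without pool 2), Mcm3, Exo1, Chek2 and Rad51ap1. Without pool 2 they were also lost for Rrm2 and Rfc4. The direction stayed the same in each.

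The ribosome, cholesterol synthesis, oxidative phosphorylation and chromatin lists also lay higher. Of 27 ribosome biogenesis and MYC target genes, 16 rose (22 adjusted over the list alone), at a median of 0.52, including the nucleolar genes Npm1 (0.96), Nop58 (0.92) and Rrs1 (0.84). Among 29 ribosomal protein genes the median was 0.29 and 0 passed singly, also when adjusted over the list alone, with Rpl7 at 0.50 (adjusted p 0.053) and Rplp0 at 0.42 (0.0552). Rpl7 passed in 7 of 14 other settings and Rplp0 in 5 of 15. Of 18 cholesterol synthesis genes, 3 rose (10 adjusted over the list alone): Hsd17b7 (0.88), Cyp51 (0.67) and Fdps (0.43). Of 33 oxidative phosphorylation genes, 2 rose, Cycs (0.66) and Atp5g1 (0.57), and 0 when adjusted over the list alone. Of 25 chromatin and polycomb genes, 8 rose and 1 fell (9 and 2 adjusted over the list alone). Hmga2, a fetal chromatin protein gene, rose by 2.09, the histone methyltransferase gene Ezh2 by 0.96 and Rnf2 by 0.68, and Smarca2 fell by 0.67. With an estimated correlation the adjusted p was 0.721 for oxidative phosphorylation and 0.638 for the other 4 lists. After cyclic loess, camera no longer passed oxidative phosphorylation (median 0.10, adjusted p 0.101), and the medians of the ribosomal protein and chromatin lists were 0.16 and 0.10. The oxidative phosphorylation median was 0.28 without tumour 1, and Atp5g1 stood at 0.23 (adjusted p 0.246) as the mean of its probe sets. Nop58, Rrs1, Rpl7, Hsd17b7 and Rnf2 lie on chromosome 1, where tumour 1 stood 0.43 higher. Without tumour 1 they were at 0.78, 0.61, 0.38, 0.88 and 0.56, and the Rrs1 call was lost (adjusted p 0.0513), as after cyclic loess (0.0513).

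Regulators of the cell cycle moved both ways. Cdkn2a, which encodes the inhibitors p16INK4a and p19ARF, rose from 7.98 ± 0.16 to 10.44 ± 0.21 (mean log2 value ± SD, n = 2), with an adjusted p of 0.00208. Its neighbour Cdkn2b rose by 0.97 and Rbl1 by 0.71, while the antiproliferative gene Btg2 fell by 1.03. The Cdkn2b call (adjusted p 0.0494) was lost without pool 1 (0.0723), pool 2 (0.206) or tumour 2 (0.122), after quantile normalization (0.0503), after cyclic loess (0.0578) and with array weights (0.0502). Of 14 growth arrest and tumour suppressor genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone). Of 24 cell cycle drivers and oncogenes, 3 rose and 1 fell, with the same counts adjusted over the list alone: Erbb3 (1.62), Myc (1.40) and Ccnd3 (0.71) rose, and Cdk6 fell (-1.01). Of 23 p53 targets, 5 fell and 1 rose (10 and 1 adjusted over the list alone), at a median of -0.28. Eda2r (-2.54), Trp53inp1 (-1.23), Ccng1 (-1.10) and Sesn2 (-0.95) fell most, while Mdm2, a target chosen after its value was seen, stood at 0.05 (adjusted p 0.866). The p53 list had an adjusted p of 0.0134 by camera and 0.638 with an estimated correlation, and camera gave 0.0541 without pool 1 and 0.0861 without tumour 1. The growth arrest and driver lists did not pass.

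Genes of hypoxia and glycolysis mostly rose. Of 31 measured, 16 rose and 1 fell (20 and 1 adjusted over the list alone), at a median of 0.76, or 0.50 without pool 2. The collagen crosslinking gene Lox (2.02), Bnip3 (1.87) and the prolyl hydroxylase gene P4ha2 (1.69) rose most, and the lactate dehydrogenase gene Ldha rose by 0.84. Epas1, which encodes HIF-2 alpha, fell by 3.44 (SE 0.13, adjusted p 0.0013). With an estimated correlation the adjusted p of the list was 0.638. Of 23 genes of the unfolded protein and amino acid response, 5 rose and 1 fell, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p 0.102) but did without pool 1 (0.00067), and Mthfd2 (1.42), Asns (0.80) and Trib3 (0.70) rose.

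**Figure D2:**
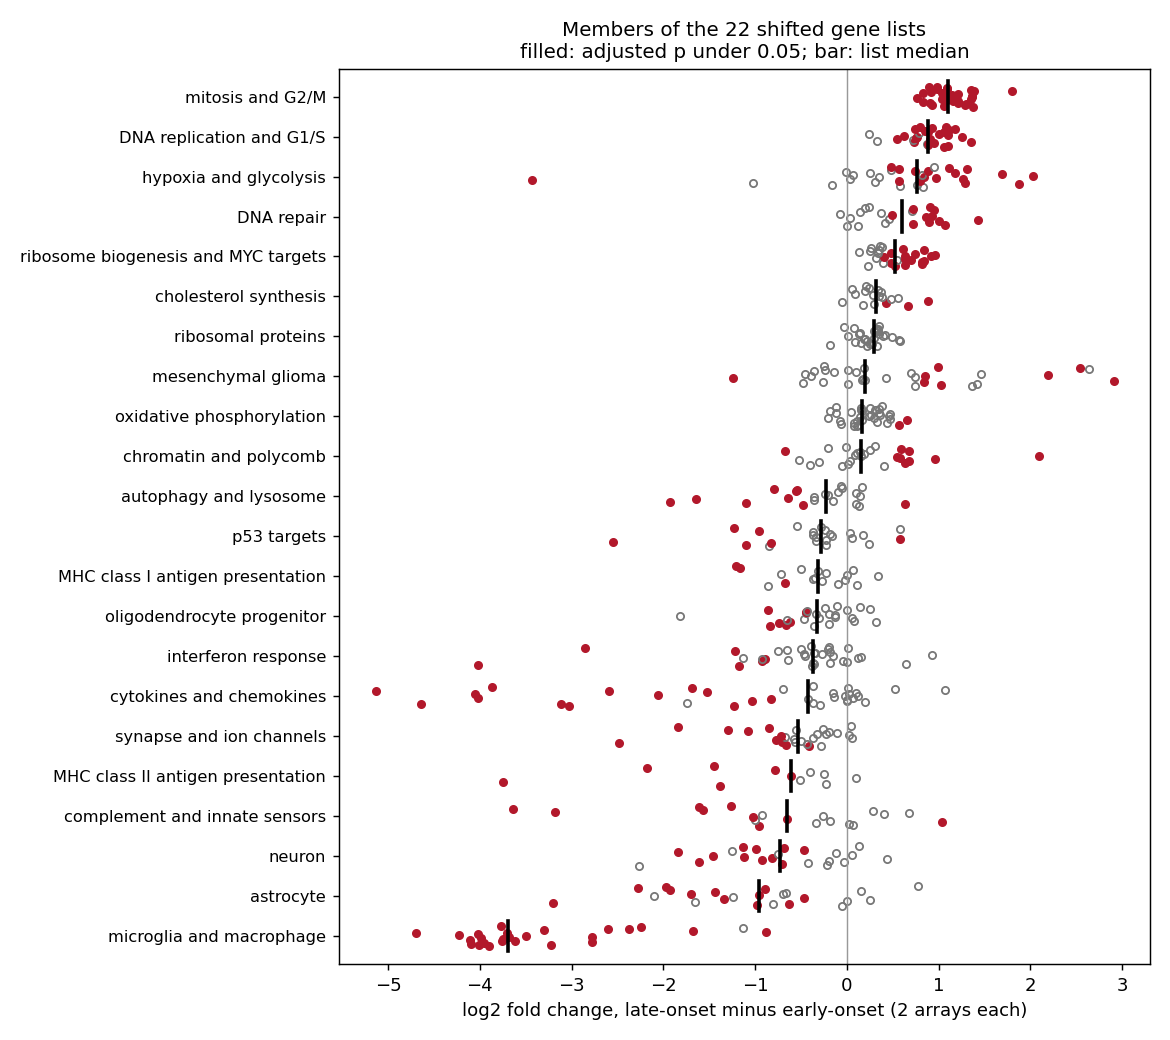
Each point is the log2 fold change (late-onset minus early-onset, 2 arrays each) of 1 member of a shifted list, filled where the gene's adjusted p was under 0.05, and the bar is the list median. The medians run from -3.69 for microglia and macrophage to 1.11 for mitosis and G2/M.

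Markers of astrocytes, neurons and glial progenitors lay lower in late-onset cells. Of 23 astrocyte markers, 12 fell (16 fell and 1 rose adjusted over the list alone), at a median of -0.95. Apoe (-3.20), which macrophages also express, the bicarbonate transporter gene Slc4a4 (-2.28), Slc7a10 (-1.97) and the glutamate transporter gene Slc1a2 (-1.93) fell most. Gfap stood at -1.25 (SE 0.44, adjusted p 0.133). It was -1.89 without tumour 2 and ranged from -1.89 to -0.60 over the 15 other settings. Of 22 neuron markers, 11 fell (14 adjusted over the list alone), including Snap25 (-1.84), Kcnc1 (-1.62), Scn2a (-1.46) and Syt1 (-1.14). Of 26 synapse and ion channel genes, 10 fell (15 adjusted over the list alone), among them the glutamate receptor gene Gria1 (-2.48), Shank1 (-1.30) and Nrxn2 (-1.07). Of 26 oligodendrocyte progenitor markers, 6 fell (11 adjusted over the list alone), at a median of -0.32, led by Rlbp1 (-0.86), C1ql1 (-0.84), Cspg5 (-0.74) and Cacng4 (-0.66). With an estimated correlation the adjusted p of each of these 4 lists was 0.638.

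The lineage factors of the tumour cells differed little. Olig2 stood at -0.19 (95% interval -0.43 to 0.05, adjusted p 0.256) and Sox10 at 0.00 (-0.24 to 0.24, adjusted p 0.997), and Sox10 was 0.06 after each array's median was subtracted. Pdgfra fell by 0.45 (adjusted p 0.041) and Pdgfb by 0.54 (adjusted p 0.032), though whether the Pdgfb probe set reads the viral transcript is not given in the sources used here. Both calls were lost without pool 1 (adjusted p 0.149 for Pdgfra and 0.155 for Pdgfb), pool 2 (0.229 and 0.167) and tumour 1 (0.0795 and 0.0766). The Pdgfra call was also lost without tumour 2 (0.105), after quantile normalization (0.0542) and after median subtraction (0.0588). Of 12 PDGF ligand and receptor genes, 3 fell, with Nrp1 (-1.45) the third, and 3 when adjusted over the list alone.

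Other neural lists moved both ways and did not pass camera. Of 23 myelinating oligodendrocyte genes, 3 rose and 4 fell (3 and 7 adjusted over the list alone), with Cldn11 (2.07) and the myelination factor gene Myrf (1.39) higher and the myelin genes Mobp (-2.62) and Mbp (-1.45) lower. Of 20 neuroblast genes, 4 rose and 1 fell (5 and 4 adjusted over the list alone): Cd24a (2.44), Tubb3 (1.86) and Sox11 (0.75) rose, and Dcx fell (-1.08). Of 24 neural stem and radial glia genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone), with Hmga2, Tnc and Nes (1.34) among those that rose. Of 20 proneural glioma genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone), with Fgf12 (-0.88) and Ptprd (-0.79) lower. The neural stem list passed as higher without pool 2 (adjusted p 0.0413) or tumour 1 (0.0235), and the myelinating list as lower without tumour 2 (0.048). Among 15 ependymal and 5 erythroid markers 0 passed, also when adjusted over the list alone. The ependymal genes Cfap126 and Dynlrb2 stood at 0.35 (adjusted p 0.072) and -0.35 (0.0879), and the erythroid genes Alas2 and Rhag at -0.26 (0.18) and -0.14 (0.5).

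Mesenchymal and stromal transcripts differed between the 2 late-onset tumours. Of 31 mesenchymal glioma genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone), at a median of 0.20. Emp1, Tnc and S100a10 (2.19) rose and Lgals3 (-1.25) fell. All 31 were higher in tumour 2 than in tumour 1, with a median gene-by-gene difference of 0.53. The list had an adjusted p of 0.0297 by camera, 0.866 with an estimated correlation, 0.531 without tumour 2, 0.0505 without pool 2 and 0.0531 among genes above the lower quartile. Its median was 0.003 without tumour 2, 0.75 without tumour 1, 0.45 without pool 1 and 0.42 without chromosome 1 genes. Several genes of fibroblasts, chosen after their values were seen, stood high in tumour 2 alone. Col1a1 was 10.23 there against 7.26 to 7.57 on the other arrays, Dcn was 9.23 against 4.96 to 6.34, and Acta2 was 10.31 against 7.12 to 7.43. The pericyte gene Rgs5 fell (-0.56), as did Vtn (-0.57), and 2 of 20 mural and fibroblast markers fell in all, also when adjusted over the list alone. Rgs5 lies on chromosome 1, and its call was lost without pool 1 (adjusted p 0.172), pool 2 (0.117), tumour 1 (0.0816) or tumour 2 (0.0533). The Vtn call was lost likewise (0.08, 0.188, 0.0762 and 0.09). The mural and fibroblast list did not pass camera (adjusted p 0.209). Without tumour 1 it passed as higher, at a median of 0.34, and without tumour 2 its median was -0.13.

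Vessel, matrix and adhesion lists did not pass camera. Of 21 endothelial markers, 1 rose, the transcription factor gene Erg (1.58), and 1 fell, Slco1a4 (-1.44), with the same counts adjusted over the list alone. The endothelial list had an adjusted p of 0.102, and it passed as lower without pool 2 (0.00403), without tumour 2 (0.0013) and with camera on ranks (0.0362). Of 34 matrix and protease genes, 5 rose and 5 fell (7 and 5 adjusted over the list alone), with the proteases and inhibitors Plau (-2.52), Ctsb (-1.90), Mmp12 (-1.60) and Timp2 (-1.57) lower. That list passed as higher without tumour 1 (adjusted p 0.00111). Of 23 integrin and adhesion genes, 3 rose and 6 fell, with the same counts adjusted over the list alone: Itgb5 (-3.36), Itga6 (-2.58) and Cdh10 (-1.01) fell, and Itga4 rose (1.77). Itgb5, Itga6, Plau, Ctsb and Mmp12 were lowest in tumour 1, like most microglia and macrophage genes, whereas Timp2 and Cdh10 were lowest in tumour 2. Which cells carried these falls was not tested.

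Signalling lists did not pass camera either. Of 25 TGF-beta and BMP genes, 1 rose and 3 fell (3 and 6 adjusted over the list alone), with the receptors Tgfbr2 (-1.35) and Tgfbr1 (-0.79) and the binding protein gene Ltbp1 (-0.95) lower and Bmp7 (1.09) higher. Of 20 Notch genes, 1 rose and 3 fell, with the same counts adjusted over the list alone: Nrarp (-1.28), Lfng (-0.96) and Dll1 (-0.63) fell, and Hey2 rose (0.95). Of 24 Wnt genes, 4 rose and 2 fell (4 and 5 adjusted over the list alone), with Dkk3 (1.36) and Fzd1 (1.16) higher and Nkd1 (-0.91) and Wnt7a (-0.78) lower. Of 11 hedgehog genes, 1 fell, Boc (-0.96), and 1 when adjusted over the list alone, and the list passed as lower by fry (adjusted p 0.0454). Of 20 MAPK feedback genes and ETS targets, 1 rose, Egr2 (1.24), and 1 when adjusted over the list alone; the list passed as higher without pool 1 (adjusted p 0.0298) or tumour 1 (0.0102). Of 29 Hox genes, 1 rose, Hoxa5 (2.16), and 1 when adjusted over the list alone. Of 22 fetal and imprinted growth genes, 3 rose and 4 fell, with the same counts adjusted over the list alone, including Dlk1 (1.66) higher and Ndn (-1.50) and Meg3 (-1.11) lower. Of 21 immediate early genes that dissociation can induce, 1 rose and 5 fell (3 and 6 adjusted over the list alone), led by Atf3 (-2.24), Zfp36 (-1.24), Btg2 (-1.03) and Klf2 (-0.99), and the list passed as lower without pool 2 (adjusted p 0.00536). Of 21 apoptosis regulators, 1 fell, Birc3 (-0.96), and 1 when adjusted over the list alone.

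Tumour 1 stood apart from the other samples over chromosome 1. Over 578 genes of chromosome 1 above the median level, its median log2 value lay 0.43 above the early-onset mean, against 0.03 in tumour 2. On the other chromosomes the medians of tumour 1 ranged from -0.02 to 0.08. Among these 578 genes, 83 rose (14.4%) and 33 fell in the comparison of groups. On the other chromosomes the share that rose was 9.21% (chromosome 8) to 14.3% (chromosome 3, where 69 rose and 49 fell). The share that rose was thus highest on chromosome 1, though close to that of chromosome 3. Whether the shift of tumour 1 added to the higher calls on chromosome 1 was not tested. Without chromosome 1 genes, an alternative chosen after the data were seen, 2899 genes changed and the same number of lists shifted, 22.

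**Figure D3:**
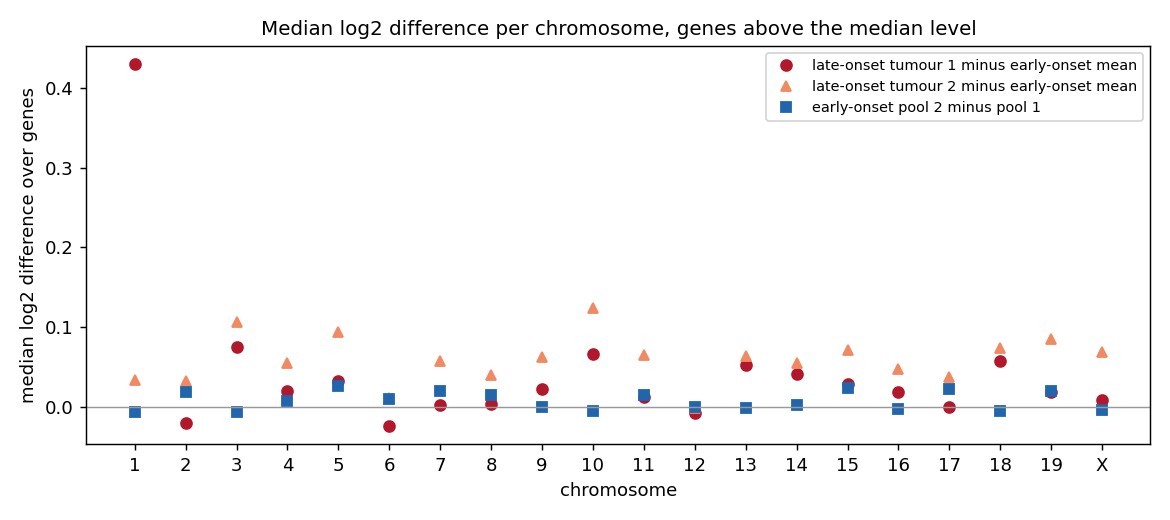
Points give the median log2 difference over the genes of each chromosome above the median level, for each late-onset tumour against the early-onset mean and for pool 2 against pool 1. Tumour 1 lies at 0.43 on chromosome 1, and no other point lies above 0.124.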

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

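The added alternatives were chosen after seeing the data. Without chromosome 1 genes 22 lists shifted, while leaving out members shared with the microglia and macrophage list took 1 gene from 1 other list and so tests nothing. The main counts were 2931 changed genes (1313 higher, 1618 lower) and 22 lists (10 higher, 12 lower). The gene count stayed within 1.5 times under the other variance models, filters, scalings, probe set choices and array weights, from 2753 to 3148. The share of higher calls moved from 44.8% to 53.8% after median subtraction and 37.8% after cyclic loess, and was 54.7% among genes above the median (1507 higher, 1246 lower). The replicate block gave 1833 genes, 744 higher and 1089 lower, and 22 lists, and 34 named calls were lost. The deviations of same-numbered samples correlated at -0.04, so the numbers show no pairing, and the block also costs 1 of the 2 residual degrees of freedom. A 2-fold minimum left 1077 (373 higher, 704 lower), and an adjusted p of 0.1 gave 4539 (2169 higher, 2370 lower), both by construction. Leaving out 1 sample gave 850 to 2577 genes, 291 to 1212 higher and 559 to 1365 lower, with fewer samples in the fit. The lists numbered 22 to 25, 9 to 14 higher and 8 to 15 lower, with 14 higher and 8 lower without tumour 1. With an estimated correlation 0 lists passed (0 higher, 0 lower), and fry passed 6 (2 higher, 4 lower). The camera test with an estimated correlation rests on the 2 residual degrees of freedom, so it could hardly pass any list. The estimated correlation between mitosis genes was 0.66. Of 165 called genes named, 70 kept their call in each setting in which they were tested, 53 of them tested in all 15, and 0 changed direction. Losses numbered 76 and 78 without pool 1 or 2, and 24 and 25 without tumour 1 or 2. Of the 22 lists, 16 kept their call in all settings other than the estimated correlation and fry, and 0 changed direction. Direction turned only for results that did not pass. For lists it is that of the test, so with 1 sample left out the matrix, fetal, apoptosis and proneural medians kept their sign. Sox10 was 0.057 after median subtraction and -0.019 to 0.017 with 1 sample left out, and Uty -4.36 to 0.61. By fry, the matrix (median 0.27), fetal (-0.10) and T and NK (0.009) lists turned, as did neuroblast on ranks (-0.062), apoptosis above the lower quartile (-0.089) and after cyclic loess (-0.10), and T and NK above the lower quartile (-0.022). With 1 sample left out the medians of the lists whose test turned ranged from -0.07 to 0.046 (Notch), -0.04 to 0.057 (T and NK), -0.204 to 0.009 (TGF-beta), -0.114 to -0.036 (apoptosis), -0.227 to 0.07 (immediate early), 0.022 to 0.548 (matrix), -0.143 to -0.035 (fetal), -0.126 to 0.337 (mural), -0.292 to 0.016 (myelin) and -0.131 to -0.057 (proneural). The cause of these turns was not tested. Signal over background limits dim genes, and log2 values near the floor understate falls.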

Other observations

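Each test of an explanation in this part was chosen after the results had been seen, although the other scalings it draws on were planned settings. Among probe sets with no gene name, 236 changed, 148 higher and 88 lower in late-onset cells. Sex-linked genes differed by sample and not by group. Xist stood at 11.71 and 11.30 in the pools, 4.97 in tumour 1 and 11.35 in tumour 2. Uty stood at 7.91 and 8.50 in the pools, 8.82 in tumour 1 and 3.85 in tumour 2. By these genes tumour 1 read as male, tumour 2 as female and both pools as mixed. Differences between the tumours are therefore also differences of sex.

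Microglia and macrophage transcripts were lower in late-onset samples. A general excess of non-tumour cells in the early-onset sorts would lower other cell types alike. Of 86 endothelial, mural, astrocyte and neuron markers, 41 had signal in the pools, and these too lay lower in late-onset samples, at a median of -0.81. That median was, however, 2.88 log2 units above that of the myeloid genes (95% interval 2.15 to 3.14). The first version of this test used 4 endothelial markers alone and gave 3.27 (2.59 to 3.73), and the wider set was chosen after that value was seen. Both go against a general excess as the whole cause, although tumour cells also express some of these markers. The sets were not matched on level. The myeloid list had medians of 10.7 and 10.3 in the pools, whereas the other markers only had to exceed 7.44. A dimmer marker has less room to fall, so the size of the gap may be overstated. Whether a general excess is a part of the cause stays open. Fewer myeloid cells or less myeloid RNA in the late-onset sorts, and whether either follows grade, age at onset or cells carried through the EGFP gate, stay open and were not tested.

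Cell cycle transcripts were higher in late-onset samples. Dilution by myeloid RNA in the pools would raise tumour cell genes alike. The oligodendrocyte progenitor median was -0.32 and lay 1.43 below the mitosis median (difference -1.43, 95% interval -1.60 to -1.23). This argues against dilution as the whole cause only if progenitor genes were otherwise steady in the tumour cells. A fall of these genes in tumour cells would hide such a rise and was not tested, so a part for dilution stays open. The mitosis median was at least 1.03 under each other scaling, so the rise did not depend on the choice among them. These scalings start from RMA values and moved the median of all genes only to between -0.02 and 0.05. They also hide a change shared by most genes, so they cannot exclude an effect of scaling. Whether the rise follows grade was not tested. Grade, age at onset and pooling of tumours coincide in these samples, so they cannot be told apart here.

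Chromosome 1 transcripts were higher in tumour 1. An extra copy of chromosome 1 may be present in cells of that tumour, since 9 of 9 bins of 60 neighbouring genes (0.36 to 0.51) lay above the highest of 148 bins elsewhere (0.20). Scaling by brightness is argued against by genes of other chromosomes matched on level, whose median averaged 0.023 over 10000 random lists, against 0.43 on chromosome 1. A few strong genes are argued against because the lowest of those bin medians, 0.36, exceeded each bin elsewhere. Copy number was not analysed here, and 3 copies instead of 2 would give a log2 step of 0.58 if expression followed.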
